A study of Mus musculus with 32 samples.

How the data were processed

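The series holds 32 libraries from the embryonic mouse thymus. Per the labels, DN1 populations were sorted by flow cytometry on BCL11b and ID2 reporters, together with DN2 cells. Per the labels' protocols, RNA was isolated with an RNeasy Plus micro kit, processed with the Ovation RNA-seq System V2, broken up on a Covaris M220 and given barcodes with an Ovation Ultralow system. The strand kept by these kits is not given in the sources used here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.50, aligned to GRCm38 with STAR 2.6.0a and normalised with DESeq2 1.18.1. The deposited values are a normalised signal, named DESeq-normalised read counts per the labels, with 1 table for each stage. Each column was divided by the value that stands for 1 read, which gave whole reads for 100% of values at both stages, within a tolerance of 0.01 reads.

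Columns were matched to samples by the numbers and names in their headers. All 14 E15.5 columns carry only a number, which was matched to the barcode number in the sample descriptions, so the E15.5 groups rest on that match. Bcl11b and Id2 had been looked at before the match was written down, but the match does not use them. The tables held 19404 genes at E15.5 and 26244 at E19.5, with 12 and 13 gene identifiers lacking a symbol in the GENCODE annotation. There were 0 entries other than genes and 0 columns of other samples.

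Tests ran on log2 of the deposited value plus 1, a scale that understates the differences of genes with few reads. Genes with a value of at least 10 in at least 3 libraries of the stage were kept, which left 10289 at E15.5 and 13840 at E19.5 and removed 9115 and 12404. All populations of a stage entered 1 linear model in limma 3.58.1 (R 4.3.3), with an intensity trend and robust moderation of the variances. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Every adjusted p given for a gene comes from this limma fit unless another tool is named.

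The comparisons, chosen before the data were examined, set the ID2-positive against the ID2-negative gate at each BCL11b state, the BCL11b-positive against the BCL11b-negative gate at each ID2 state, and DN2 against the BCL11b+ID2- gate. The interaction, the ID2 difference among BCL11b-positive cells minus that among BCL11b-negative cells, was tested at both stages. At E19.5 the BCL11blowID2low gate was set against the BCL11b-ID2- and the BCL11b+ID2+ gates. This made 14 comparisons. The difference between E19.5 and E15.5 over the 4 shared gates, and the stage difference of the gate effects, were planned but not run, because the stages were normalised in separate tables. A comparison of the BCL11blowID2low gate with the BCL11b+ID2- gate was added after the data had been seen and stands in the closing section.

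Gene lists fixed before the data were examined were tested with camera in limma at its preset correlation of 0.01, and again with a correlation estimated from each list. P-values were adjusted over all lists and comparisons of a stage, 138 tests at E15.5 and 184 at E19.5. The 23 lists are lineage regulators with the reporter genes, T-cell receptor complex and signalling, Notch pathway, progenitor regulators, innate lymphoid precursor, ILC2, type 3 ILC, NK cell and ILC1, gamma-delta T cell, alpha-beta thymocyte and B-lineage genes. Further lists hold markers of other cells, namely macrophage, monocyte and granulocyte, dendritic, erythroid with megakaryocyte and mast cell, and thymic epithelial and stromal genes. The others are cell cycle, chemokine receptor and homing, cytokine receptor, cytokine and effector, interferon response, immediate early and dissociation stress, glycolysis and mitochondrial genes. Counts of list members called are over all genes, and counts adjusted over the list alone stand beside them. Lineage regulators include Bcl11b and Id2, and innate lymphoid precursor genes include Id2. Part of a difference of these lists between gates can therefore follow from the sort itself. The lists were not tested without these genes.

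Genes were named by a rule written before the data were examined. It takes genes with adjusted p under 0.05, no overlap between the libraries of the groups and a mean of at least 100 in the higher group, up to 12 per direction by log2 difference, leaving out predicted, mitochondrial and ribosomal genes. Members of the fixed lists that passed were also eligible, shorter runs were given for DN2, the interactions and the BCL11blowID2low gate, and where fewer than 3 genes passed the ones with the smallest p are given as not passing. Some genes that met the rule are not reported here. Folds are ratios of mean values. A fold against a group with no reads is a lower bound taken at a floor of 3 reads over the group. With 1 to 3 reads in a group the ratio has a 95% counting interval, and these floors and intervals cover counting error only, not the spread between libraries. Coordinates are those of GENCODE genes on GRCm38. Receptor segments, Klr genes, granzymes and mast cell proteases have close relatives, so reads may be divided among them.

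Depth limits what low genes can show. A mean of 1.58 normalised counts in the BCL11b+ID2- gate of E15.5, and of 1.74 at E19.5, corresponds to the floor of 3 reads. The procedure was tested on simulated data, with counts drawn from each gene's mean and dispersion in the stage's libraries and 200 genes changed by known folds in the BCL11b+ID2+ gate, for the comparison of that gate with BCL11b+ID2-. At E15.5 (10289 genes) limma recovered 0 of 48 genes changed 2-fold, 0 of 47 changed 4-fold, 2 of 50 changed 8-fold and 7 of 48 changed 32-fold, a size added after a first run with the smaller ones had recovered none. It made 1 false call among 10, against 99 among 123 for DESeq2. At E19.5 (13840 genes) limma recovered 2 of 45, 18 of 48, 28 of 49 and 42 of 50 at the same sizes, with 7 false calls among 97.

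The alternatives were a pseudocount of 8, no filter, TMM scaling, quasi-likelihood tests in edgeR 4.0.16 and Wald tests in DESeq2 1.42.0 on the recovered reads, a fit of only the groups compared, library weights, a block for the number shared by libraries, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.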

Results

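Bulk RNA-seq was carried out on cells flow-sorted from the embryonic thymus of a mouse reporter strain, named 5x polychromILC in the labels, at stages E15.5 and E19.5. Most of the populations are labelled DN1, a name for the earliest of the thymocyte stages that lack CD4 and CD8, and they were divided by BCL11b and ID2. BCL11b is a transcription factor switched on as thymocytes commit to the T-cell lineage. ID2 blocks E-protein transcription factors and is high in innate lymphoid cells (ILCs) and their precursors. Each stage held 4 DN1 gates, positive or negative for each reporter, and E19.5 held a further DN1 gate that was low for both, written BCL11blowID2low here. DN2 cells, by name the stage after DN1, were sorted at both stages as a reference. Each population had 3 libraries, apart from DN2 at E15.5 with 2, giving 14 libraries at E15.5 and 18 at E19.5. Nothing in the labels says that libraries of a population came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

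Depth differed between the stages. Reads recovered from the deposited values came to 12030749 to 20709387 per library at E15.5 and 2599470 to 9498133 at E19.5. The genes mt-Rnr1 and mt-Rnr2, the mitochondrial ribosomal RNAs, took 50.8 to 80.0% of them at E15.5 and 28.7 to 58.8% at E19.5. Without mitochondrial genes, 3393061 to 7808245 and 1762514 to 5161153 reads were left. The deeper E15.5 libraries nevertheless detected fewer genes, 8277 to 12954 against 14387 to 18879.

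The 2 sorting genes were read first, as a check of the labels. Bcl11b (chromosome 12, 107910403 to 108003602, GRCm38) stood at E19.5 at 1674 ± 348 normalised counts (mean ± SD, n = 3, as throughout for E19.5) in the BCL11b+ID2- gate and at 515 ± 95.7 in the BCL11b+ID2+ gate. The BCL11b-ID2- and BCL11b-ID2+ gates held 16.3 ± 13 and 26.7 ± 10.9, the BCL11blowID2low gate 448 ± 62.5 and DN2 692 ± 377. Id2 (chromosome 12, 25093799 to 25097140, GRCm38) stood at 1119 ± 138 and 1438 ± 140.0 in the BCL11b+ID2+ and BCL11b-ID2+ gates, and at 19.6 ± 15.9 and 21.2 ± 3.2 in the ID2-negative ones. It was intermediate, 169 ± 12.2, in the BCL11blowID2low gate and 14.8 ± 11.7 in DN2.

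At E15.5 both genes followed the gates less tightly. Bcl11b stood at 2294 ± 1903 (n = 3) in the BCL11b+ID2- gate, 3172 ± 2105 in BCL11b+ID2+, 22.3 ± 16.6 in BCL11b-ID2- and 191 ± 277 in BCL11b-ID2+, where library 1 alone held 509. DN2 stood at 1611 ± 1046 (n = 2). Id2 was 1047 ± 1497 in BCL11b+ID2+ and 1428 ± 927 in BCL11b-ID2+, against 2.66 ± 2.33 in BCL11b+ID2-, 60.7 ± 57.3 in BCL11b-ID2- and 10.4 ± 9.48 in DN2. Library 1 of the BCL11b+ID2+ gate, at 85, lay below library 1 of the BCL11b-ID2- gate, at 126. Id2 did not pass in either ID2 comparison at E15.5, with adjusted p = 0.061 among BCL11b-positive and 0.347 among BCL11b-negative cells in the limma fit. Bcl11b, for its part, was not called in either BCL11b comparison at E15.5.

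**Figure D1:**
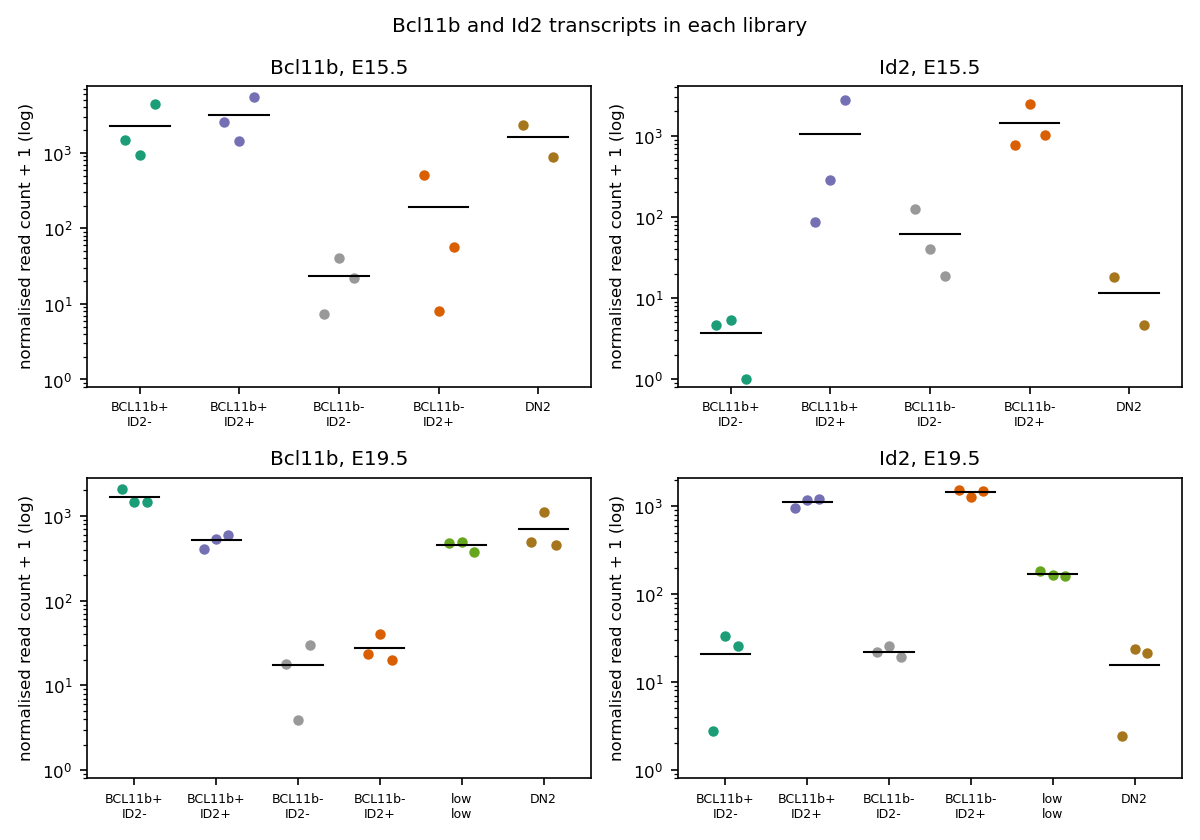
Normalised read counts plus 1 of Bcl11b and Id2 (log axes), a point per library and a bar at each population's mean, for the populations of E15.5 (top) and E19.5 (bottom). At E19.5 the Bcl11b and Id2 means of positive and negative gates are far apart and the low/low gate has an Id2 mean of 169 ± 12.2, while at E15.5 libraries of the same gate are widely spread.

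The first question is which transcripts go with ID2 among BCL11b-positive DN1 cells, and at E15.5 the BCL11b+ID2+ gate was set against the BCL11b+ID2- gate. Jag1, a Notch ligand, stood at 1281 ± 299.7 against 1.66 ± 1.32 normalised counts (SD, n = 3 per gate), a 772-fold difference (log2 difference 8.99 ± 1.77 SE, adjusted p = 0.0159). Il18rap, an IL-18 receptor subunit, rose 691-fold (adjusted p = 0.0274), and the chemokine receptor gene Cxcr6 rose 295-fold. Arg1, the arginase of ILC precursors and type 2 ILCs (ILC2), rose from 29.6 ± 41.5 to 3607 ± 2723 (adjusted p = 0.0379). In the other direction, Erg, an Ets-family factor of stem and progenitor cells, was 344-fold lower at 18 ± 9.99 against 6194 ± 3411 (adjusted p = 0.000868). Notch3 was 1034-fold (95% counting interval 286 to 8534) lower. Further genes of the ranking that rose were Adam12, Cd200r1, Ankrd50, Myo6, Clnk and Trio, with log2 differences from 7.64 to 8.79. Those that fell were Gfra1, Ptprf, Akr1b3, Tmem151b, Aff3, Camk2a and Smo, and Trbv13-2, a receptor segment whose reads may be shared with similar segments.

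For the fixed gene lists, a rise or fall given with 1 adjusted p also held with an estimated correlation. Chemokine receptor and homing genes rose (adjusted p = 1.67e-07) in 4 of 22 with 1 moving the other way (8 adjusted over the list alone), with Cxcr6, Itgae and Cd44 higher. Innate lymphoid precursor genes rose in 3 of 14 (5 adjusted over the list alone, adjusted p = 5.63e-07), namely Cxcr6, Arg1 and Il18r1. ILC2 genes rose in 2 of 16 (6 adjusted over the list alone, adjusted p = 7.14e-06), namely Arg1 and Rora. Notch pathway genes fell (adjusted p = 0.000425), with Notch3 the member called of 8 (3 adjusted over the list alone). Later alpha-beta thymocyte genes fell too (adjusted p = 0.00057), with 3 of 10 (3 adjusted over the list alone) lower, Rag1, Rag2 and Arpp21. A further 5 lists passed only with the preset correlation. Lineage regulators (Rora, Maf) rose (adjusted p = 0.0246, adjusted p = 0.288 with an estimated correlation). Cytokine receptors (Il18rap, Il18r1) rose (adjusted p = 0.037, adjusted p = 0.158 with an estimated correlation). T-cell receptor genes (Rag1, Rag2) fell (adjusted p = 0.0409, adjusted p = 0.138 with an estimated correlation). Progenitor regulators fell (Erg and Lin28b, with Lmo4 higher, adjusted p = 0.0178, adjusted p = 0.103 with an estimated correlation). Stromal genes fell with none called (adjusted p = 0.0409, adjusted p = 0.293 with an estimated correlation). Apart from the stromal list, markers of other cells did not pass as lists, although Cpa3, a mast cell protease, was called lower. In all, 74 of 10289 genes changed, 41 higher and 33 lower, against a median log2 difference of all genes of -0.22. The split was 45 higher to 17 lower with edgeR, but more genes were lower with DESeq2, 515 to 574, without the filter, 10 to 11, and without libraries 1, 2 or 3 of BCL11b+ID2+, 6 to 16, 33 to 49 and 3 to 12. A fit of these 6 libraries alone called 2 genes.

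Among BCL11b-negative DN1 cells at E15.5, the ID2-positive gate carried a natural killer (NK) cell programme. Il2rb, the shared IL-2 and IL-15 receptor chain, stood at 5834 ± 1653 against 7.65 ± 7.97 (SD, n = 3 per gate), 762-fold higher (log2 difference 9.92 ± 1.70 SE, adjusted p = 0.00613). Ncr1, an activating NK receptor, rose 813-fold (adjusted p = 0.0171), and the lectin-like receptor genes Klri2, Klrk1, Klrc1 and Klrb1b rose 913-fold, 1069-fold, 1065-fold and 669-fold, although reads of this similar family may be divided among its members. Tissue-retention integrins Itgae and Itga1 rose 601-fold and 441-fold. Mpo, the myeloperoxidase of myeloid progenitors, had 394 ± 177 in the BCL11b-ID2- gate and no reads in the other, so it was at least 336-fold lower (adjusted p = 0.0201). Erg and Rag2 were 65.1-fold and 88.8-fold lower. Tnfrsf9, Cd200r4, Slamf7 and Stk39 also rose, and Plekha7, Pdgfrb, Itih5, Adgrg1, Angpt1, Spns2, Bpifc and Ripor1 fell.

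The NK cell and ILC1 list rose with 6 of 18 (13 adjusted over the list alone) called (adjusted p = 4e-21, median log2 difference 7.01, 7.31 with genes at 0 in 1 gate held at their bound), among them Klrb1c and Xcl1. Innate lymphoid precursor genes rose (adjusted p = 1.67e-07), with 4 of 14 (8 adjusted over the list alone) higher: Arg1, Cxcr6, Ets1 and Il18r1. Homing genes rose in 3 of 22 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 1.73e-05). Of cytokine and effector genes, 1 of 9 (5 adjusted over the list alone) was called, Xcl1, and the list rose (adjusted p = 1.67e-07). ILC2 genes rose in 2 of 16 (6 adjusted over the list alone, adjusted p = 0.00667), Rora and Arg1. Progenitor regulators fell (adjusted p = 4.14e-05) with 1 of 13 (4 adjusted over the list alone) called, Erg. Notch pathway genes fell with 0 of 8 called and 3 adjusted over the list alone (adjusted p = 1.17e-05). Lineage regulators rose (adjusted p = 1.94e-05, adjusted p = 0.0767 with an estimated correlation). So did type 3 ILC genes (adjusted p = 0.0478, adjusted p = 0.272 with an estimated correlation). Alpha-beta genes fell (adjusted p = 0.0478, adjusted p = 0.131 with an estimated correlation). Mitochondrial transcripts, a sign of RNA quality, rose (adjusted p = 0.0246, adjusted p = 0.536 with an estimated correlation). Of the markers of other cells, Mpo and the pericyte gene Pdgfrb fell singly and their lists did not pass. Altogether 48 genes changed, 33 higher and 15 lower. Library weights gave 146 and leaving out library 3 of the BCL11b-ID2- gate 4. The excess of higher genes turned without any library of the BCL11b-ID2+ gate, to 3 higher and 6 lower without library 1, 4 and 6 without library 2 and 2 and 6 without library 3.

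Comparing the ID2-negative gates asks what goes with BCL11b. At E15.5 only 1 gene passed in BCL11b+ID2- against BCL11b-ID2-, namely Ets1, which encodes a factor needed for T and NK cell development. It stood at 1077 ± 577 against 17.2 ± 10.6 (n = 3 per gate), 62.5-fold higher (log2 difference 6.02 ± 1.04 SE, adjusted p = 0.0479). Nav2 at 3378 ± 2353 against 7.26 ± 6.09 and Themis at 2988 ± 443 against 66.6 ± 60.2, the next by p, did not pass (adjusted p = 0.118 for both). As groups, T-cell receptor genes rose with 0 of 16 called and 6 adjusted over the list alone (adjusted p = 3.41e-09, median log2 difference 2.23). Gamma-delta T cell genes (adjusted p = 0.000522, 2 of 13 adjusted over the list alone) and alpha-beta genes (adjusted p = 3.68e-05, 3 of 10 adjusted over the list alone) rose with none called over all genes. Macrophage, monocyte and granulocyte genes fell (adjusted p = 4.72e-06, 4 of 11 adjusted over the list alone). Mitochondrial transcripts rose beside them (adjusted p = 3.55e-11, adjusted p = 0.11 with an estimated correlation). Lineage regulators rose (adjusted p = 0.011, adjusted p = 0.245 with an estimated correlation), and so did ILC2 genes (adjusted p = 0.00955, adjusted p = 0.0501 with an estimated correlation). Cell cycle genes rose too (adjusted p = 0.0109, adjusted p = 0.11 with an estimated correlation). Progenitor regulators fell (adjusted p = 0.0208, adjusted p = 0.109 with an estimated correlation), and so did mast and erythroid genes (adjusted p = 0.0153, adjusted p = 0.099 with an estimated correlation). The test called 1 of 10289 genes with 704 at an unadjusted p under 0.05. The call of Ets1 was lost with a pseudocount of 8, without the filter, under TMM scaling and with edgeR, each at 0 genes. A fit of only the groups compared and the block for the library number also gave 0 genes. No fit without a single library kept Ets1, while DESeq2 called 335 genes, 113 higher and 222 lower.

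Between the ID2-positive gates of E15.5, 8 genes changed. Dpp4, the surface peptidase CD26, stood at 7591 ± 9887 against 67.9 ± 62.7 (n = 3 per gate) in BCL11b+ID2+ against BCL11b-ID2+, 112-fold higher (log2 difference 6.34 ± 1.09 SE, adjusted p = 0.0108). The receptor constant genes Tcrg-C1 and Tcrg-C2 rose 18.6-fold and 139.6-fold, with reads that similar constant genes may share, and the G1 kinase gene Cdk6 rose 3.96-fold. Cpa3 was 257-fold lower at 7.85 ± 6.86 against 2020.1 ± 1499.7 (adjusted p = 0.00217), and Uprt was 139-fold lower. Ncr1 and Cd200r4 had almost no reads in BCL11b+ID2+, 1297-fold (95% counting interval 359 to 10711) and 5022-fold (95% counting interval 901 to 198344) lower. NK cell genes fell as a group (adjusted p = 7.71e-19), with 1 of 18 (16 adjusted over the list alone) lower. Cytokine and effector genes fell with none called over all genes and 5 of 9 adjusted over the list alone (adjusted p = 1.92e-05). ILC2 genes rose with 0 of 16 called and 0 adjusted over the list alone (adjusted p = 7.04e-06, median log2 difference 2.43, unchanged with genes at 0 in 1 gate held at their bound). Gamma-delta genes rose in 2 of 13 (3 adjusted over the list alone, adjusted p = 0.000188). Erythroid, megakaryocyte and mast cell genes fell (adjusted p = 0.000522), with Cpa3 called of 3 (2 adjusted over the list alone). Notch genes rose (adjusted p = 0.0305, adjusted p = 0.109 with an estimated correlation), as did cell cycle genes (adjusted p = 0.0101, adjusted p = 0.109 with an estimated correlation). Mitochondrial genes rose too (adjusted p = 0.00755, adjusted p = 0.47 with an estimated correlation). The median log2 difference of all genes was -0.44, and a fit of the 6 libraries alone called 0 genes. The split of 4 higher and 4 lower became 6 and 3 with edgeR, 4 and 15 with a pseudocount of 8, and 198 and 436 with DESeq2.

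Neither of the remaining E15.5 comparisons called a gene in limma. DN2 (n = 2) against BCL11b+ID2- (n = 3) had its smallest p at Ppm1h (2.05 ± 2.9 against 968 ± 759.8), Parp8 (0.342 ± 0.483 against 320.3 ± 117) and Myo1g (1113 ± 889 against 5.48 ± 7.5), none passing (adjusted p = 0.348). It had 663 genes at an unadjusted p under 0.05, 0 calls with edgeR and 532 with DESeq2. Stromal (adjusted p = 0.0151, adjusted p = 0.235 with an estimated correlation) and mitochondrial genes (adjusted p = 0.0131, adjusted p = 0.497 with an estimated correlation) fell. The interaction, which asks whether the ID2 difference itself depends on BCL11b, had Gzma, Gxylt1 and Gimap4 at its smallest p, with log2 differences of -6.67 ± 1.46, 9.25 ± 2.1 and -11.70 ± 2.70 SE (adjusted p = 0.454 for each). It had 662 genes at an unadjusted p under 0.05, 0 with edgeR and 392 with DESeq2. NK cell genes were nevertheless more negative as a group in the interaction (adjusted p = 2.08e-14, 6 of 18 adjusted over the list alone), and so were cytokine and effector genes (adjusted p = 0.000162). T-cell receptor (adjusted p = 0.0109, adjusted p = 0.0767 with an estimated correlation) and mitochondrial genes (adjusted p = 0.0176, adjusted p = 0.505 with an estimated correlation) passed, downward, only with the preset correlation. Most of the E15.5 calls named above depend on the processing. Of 71 named calls, a gene counted in each of its comparisons, 64 were lost in at least 1 fit without a single library, 48 with only the groups compared, 38 without the filter, 28 with edgeR and 24 with library weights.

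At E19.5 the BCL11b+ID2+ gate differed from the BCL11b+ID2- gate by an ILC2 programme. Il1rl1, the IL-33 receptor ST2, stood at 3624 ± 389 against 0.615 ± 1.07, 5894-fold (95% counting interval 1632 to 48669) higher (log2 difference 11.32 ± 0.70 SE, adjusted p = 2.22e-10). Cysltr1, a receptor for cysteinyl leukotrienes, rose 480.5-fold, Calca, which encodes the peptide CGRP, 186-fold, and the leukotriene B4 receptor gene Ltb4r1 244-fold (95% counting interval 67.5 to 2014). Fgl2 rose from 20.6 ± 6.47 to 2974 ± 606. Lower were Etv5, an Ets-family factor, at 25.8 ± 37.9 against 2399 ± 922 (93-fold, adjusted p = 9.9e-06) and Gzma, granzyme A, at 77.8 ± 32.9 against 4968 ± 557 (63.9-fold, adjusted p = 9.34e-12). Gfra1 was 134-fold and Notch3 135-fold (95% counting interval 37.3 to 1112) lower, and the delta-chain segment Trdv5 (chromosome 14, 54148662 to 54149294, GRCm38) fell from 133 ± 28.9 to 0.22 ± 0.381, although similar segments may share reads. Stab2, Pard3, Neurl3, Pde7b, Rnf128, Hs3st1 and Dlg5 also rose, and Iqch, Slc16a5, Ephb2, Zbtb8b, St8sia1, Arfgef3 and Dzip1 fell.

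ILC2 genes rose in 12 of 22 (13 adjusted over the list alone) and fell in none (adjusted p = 2.61e-14, median log2 difference 3.59, unchanged with genes at 0 in 1 gate held at their bound), with Il13, Nmur1, Klrg1, Pparg and Icos among them. Macrophage, monocyte and granulocyte genes rose with them in 13 of 18 (13 adjusted over the list alone, adjusted p = 5.48e-09), with C1qb at 174 ± 110.1 against 13.8 ± 12.2 and Csf1r at 146 ± 64.1 against 1.07 ± 1.86. Cytokine receptors rose in 11 of 26 with 3 moving the other way (13 adjusted over the list alone, adjusted p = 4.73e-06), among them Il2ra and Il9r. Innate lymphoid precursor genes rose in 8 of 16 with 3 moving the other way (8 adjusted over the list alone, adjusted p = 0.0012), among them Il7r and Cxcr6. T-cell receptor genes fell in 9 of 22 (11 adjusted over the list alone, adjusted p = 8.33e-09), among them Cd3d, Cd3e and Cd247. Gamma-delta T cell genes fell in 9 of 19 (11 adjusted over the list alone, adjusted p = 5.04e-13), with Sox13, Trdc and Cd27. Alpha-beta genes fell in 8 of 15 (8 adjusted over the list alone, adjusted p = 3.67e-08), with Tcf7, Satb1 and Trac. Progenitor regulators rose (adjusted p = 0.011, adjusted p = 0.0504 with an estimated correlation). Rises were also seen for homing genes (adjusted p = 0.0122, adjusted p = 0.07 with an estimated correlation) and interferon response genes (adjusted p = 0.0131, adjusted p = 0.146 with an estimated correlation). Immediate early and dissociation stress genes, among them Junb, Zfp36 and Dusp1, rose (adjusted p = 0.0106, adjusted p = 0.411 with an estimated correlation). Glycolysis genes rose (adjusted p = 0.0364, adjusted p = 0.467 with an estimated correlation) and cell cycle genes fell (adjusted p = 0.00327, adjusted p = 0.0984 with an estimated correlation). Across the transcriptome 1208 of 13840 genes changed, 708 higher and 500 lower. Without BCL11b+ID2- library 1 the count was 795, and without BCL11b+ID2+ library 4 it was 801.

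**Figure D2:**
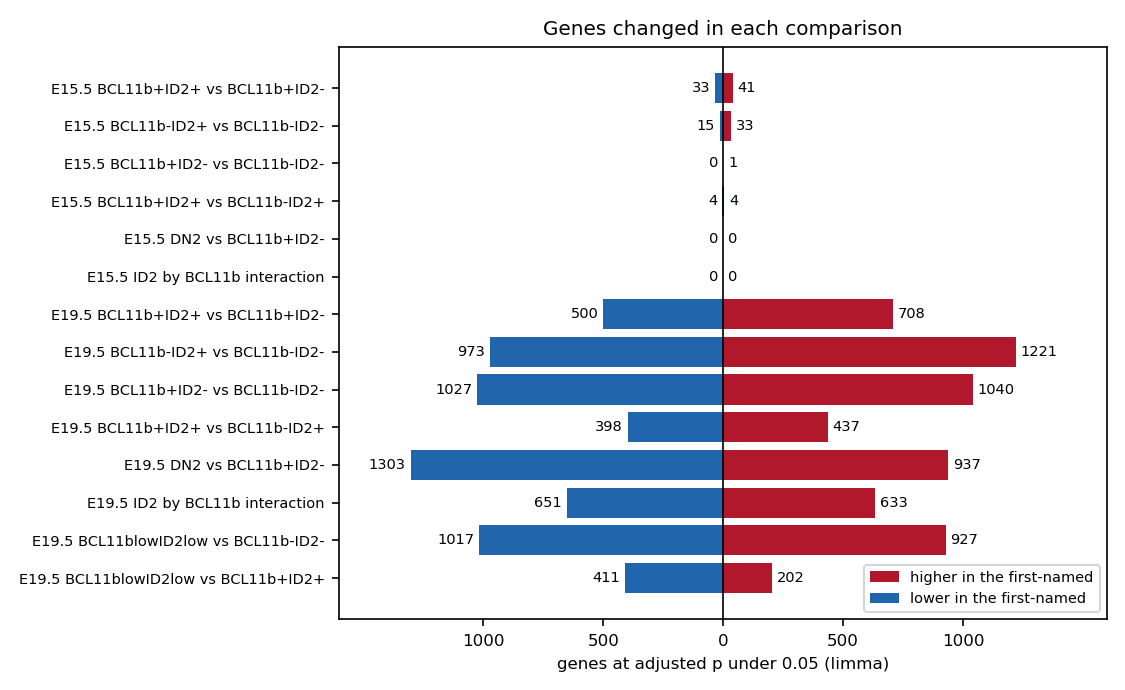
Number of genes with adjusted p under 0.05 (limma), higher to the right and lower to the left in the first-named population, for the 14 comparisons made within a stage. E15.5 comparisons call 0 to 74 genes and E19.5 comparisons 613 to 2240.

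Among BCL11b-negative cells at E19.5, ID2 again went with NK cell and effector genes. Gzmc, a granzyme, stood at 5908 ± 1031 against 15.9 ± 11.3 in BCL11b-ID2+ against BCL11b-ID2-, 371-fold higher (log2 difference 8.63 ± 0.74 SE, adjusted p = 1.47e-08). Klrc1, Klrb1b and Klrk1, lectin-like NK receptors, rose 2264-fold (95% counting interval 406 to 89417), 380.4-fold and 381-fold, and the chemokine gene Ccl1 and its receptor Ccr8 rose 1111-fold (95% counting interval 199 to 43869) and 136-fold. The mast cell protease genes Mcpt1, Mcpt2, Mcpt4 and Tpsb2 rose, with Mcpt2 at 636 ± 53.1 against 0.241 ± 0.418 and Mcpt4 at least 390.4-fold higher. These proteases, like the granzymes and Klr genes, are close relatives among which reads may be divided. Which cells of the gate the protease transcripts come from was not tested. Mpo was 1575-fold lower, from 2051 ± 456 to 1.3 ± 0.62 (adjusted p = 8.86e-09). Erg and Angpt1, the ligand of the TIE2 receptor, were 152-fold and 237-fold lower. Arnt2 and Cd101 also rose, and Igfbp4, Hnf4a, Prg2, Adgrg1, Nfe2, Ly6d and Cd33 fell.

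NK cell and ILC1 genes rose in 19 of 22 (20 adjusted over the list alone, adjusted p = 3.15e-26, median log2 difference 6.15), including the T-box factors Tbx21 and Eomes, Prf1 and Ifng. Innate lymphoid precursor genes, a list that holds the sorting gene Id2, rose in 11 of 16 with 1 moving the other way (14 adjusted over the list alone, adjusted p = 3.9e-11), with Nfil3 and Zbtb16. Homing genes rose in 17 of 24 with 4 moving the other way (18 adjusted over the list alone, adjusted p = 4.39e-09), with Itgae and Cx3cr1. Cytokine and effector genes rose in 11 of 20 (12 adjusted over the list alone, adjusted p = 3.81e-08). Lineage regulators rose in 13 of 26 with 5 moving the other way (18 adjusted over the list alone, adjusted p = 1.11e-06). T-cell receptor genes rose in 8 of 22 with 3 moving the other way (10 adjusted over the list alone, adjusted p = 5.16e-05), with Cd3g, Zap70 and Cd247. Progenitor regulators fell in 16 of 19 (16 adjusted over the list alone, adjusted p = 7.36e-15), among them Cd34, Flt3 and Kit. B-lineage genes fell in 8 of 9 (8 adjusted over the list alone, adjusted p = 1.16e-07), among them Ebf1 and Pax5. Notch genes fell in 4 of 9 (5 adjusted over the list alone, adjusted p = 0.00256). Stromal genes fell in 4 of 9 (7 adjusted over the list alone, adjusted p = 0.00074), with Pdgfrb and Psmb11. ILC2 genes rose (adjusted p = 0.0436, adjusted p = 0.0663 with an estimated correlation), as did type 3 ILC genes (adjusted p = 0.0096, adjusted p = 0.0769 with an estimated correlation). Interferon response genes rose (adjusted p = 0.0436, adjusted p = 0.234 with an estimated correlation) and macrophage genes fell (adjusted p = 0.00349, adjusted p = 0.152 with an estimated correlation). Gamma-delta genes did not pass (adjusted p = 0.12), nor did alpha-beta genes, whose median (0.41) and mean (-0.28) differed in sign (adjusted p = 0.222). In total 2194 genes changed, 1221 higher and 973 lower.

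The ID2-negative gates of E19.5 differed by gamma-delta T cell genes on the BCL11b-positive side and by progenitor and myeloid genes on the other. Tcrg-V4 (chromosome 13, 19184974 to 19185506, GRCm38), a gamma-chain variable segment, stood at 431 ± 98.1 against 1.6 ± 2.77 in BCL11b+ID2- against BCL11b-ID2-, 269.5-fold higher (log2 difference 7.89 ± 0.76 SE, adjusted p = 1.1e-07). Ccr4, a chemokine receptor of T cells, rose 75.3-fold and Bcl11b itself 103-fold (adjusted p = 1.1e-09). Mpo was 1334-fold lower at 1.54 ± 2.66 against 2051 ± 456, and Bcl11a, a factor of lymphoid progenitors and B cells, had 999 ± 32.6 in BCL11b-ID2- and was 3249-fold (95% counting interval 583 to 128315) lower (adjusted p = 5.51e-08). Erg and the cytokine receptor gene Flt3 had no reads in BCL11b+ID2-, so they were at least 370.0-fold and at least 121-fold lower, and Spi1, the myeloid factor PU.1, was 785-fold (95% counting interval 141 to 31022) lower. Sema4f, Olfr524, Slc16a5, Tox2, Trdv5, Mturn, Lingo4 and Iqch also rose, and Mef2c, Cd33, Deptor, Map3k20, Adgrg1, Ccl9 and Prg2 fell.

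Gamma-delta T cell genes rose in 18 of 19 (18 adjusted over the list alone, adjusted p = 6.61e-28, median log2 difference 4.93, unchanged with genes at 0 in 1 gate held at their bound), among them Blk, Sox13, Trdc and Il17a. T-cell receptor genes rose in 13 of 22 with 2 moving the other way (14 adjusted over the list alone, adjusted p = 2.34e-14), with Zap70, Cd3e and Themis. Alpha-beta genes rose in 10 of 15 with 1 moving the other way (12 adjusted over the list alone, adjusted p = 1.05e-08). Lineage regulators rose in 14 of 26 with 2 moving the other way (14 adjusted over the list alone, adjusted p = 1.25e-09) with Lef1, Gata3 and Tcf7. Innate lymphoid precursor genes rose in 10 of 16 with 1 moving the other way (12 adjusted over the list alone, adjusted p = 3.54e-10) with Pdcd1 and Zbtb16. Homing genes, Ccr9 among them, rose in 14 of 24 with 4 moving the other way (16 adjusted over the list alone, adjusted p = 3.8e-07). ILC2 genes rose in 7 of 22 with 4 moving the other way (7 adjusted over the list alone, adjusted p = 0.00368). Type 3 ILC genes rose in 8 of 18 with 1 moving the other way (10 adjusted over the list alone, adjusted p = 0.000247), with Il17f and Il23r. Progenitor regulators fell in 17 of 19 (17 adjusted over the list alone, adjusted p = 1.75e-22, median log2 difference -6.34, -5.80 with genes at 0 in 1 gate held at their bound). Of other lineages, macrophage, monocyte and granulocyte genes fell in 11 of 18 (12 adjusted over the list alone, adjusted p = 3.9e-11). B-lineage genes fell in 7 of 9 with 1 moving the other way (7 adjusted over the list alone, adjusted p = 4.49e-06). Dendritic cell genes fell in 7 of 12 (8 adjusted over the list alone, adjusted p = 0.00016). Lyz2 had 102 ± 28.5 in BCL11b-ID2- and no reads in BCL11b+ID2-, and Cd74 stood at 356 ± 94.5 and 30.5 ± 42.7. Erythroid and mast cell genes fell (adjusted p = 0.00603, adjusted p = 0.0663 with an estimated correlation), as did stromal genes (adjusted p = 0.0316, adjusted p = 0.124 with an estimated correlation). The test called 2067 genes, 1040 higher and 1027 lower. Lower genes led without the filter, 980 higher to 1070 lower, under TMM scaling, 993 to 1054, with the block for the library number, 1184 to 1187, and without libraries 2 or 4 of BCL11b+ID2-, 855 to 945 and 951 to 1010.

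With ID2 on in both gates at E19.5, ILC2 genes were higher in the BCL11b-positive gate and NK cell genes in the BCL11b-negative one. Pparg, a nuclear receptor of ILC2 and fat cells, had 245 ± 76.8 in BCL11b+ID2+ and no reads in BCL11b-ID2+, at least 319-fold higher (adjusted p = 4.98e-05). Ltb4r1 and Mrc1, a mannose receptor of macrophages, were at least 297-fold and at least 267-fold higher, Igf1 649-fold (95% counting interval 179.7 to 5359.9) and Ccr6 253-fold. The circadian-family factor Hlf rose from 16.1 ± 16.6 to 1718 ± 257. Xcl1, an NK cell chemokine, was 528-fold lower at 3.54 ± 4.68 against 1869 ± 888 (log2 difference -9.15 ± 0.98 SE, adjusted p = 1.57e-06), Gzmc 351-fold and Klrd1 1023-fold (95% counting interval 283 to 8446) lower. Pard3, Tlr1, Vcam1, Tnfrsf19, Slc40a1 and Calca also rose, and Ccl1, Klra5, Cd244a, Fgd5, Car2, Pdzk1, Sh2d1b1, Ptger3 and Klrb1c fell.

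ILC2 genes rose in 17 of 22 (20 adjusted over the list alone, adjusted p = 1.99e-27, median log2 difference 3.82, unchanged with genes at 0 in 1 gate held at their bound), with Gata3, Il17rb, Il4 and Nmur1. NK cell and ILC1 genes fell in 19 of 22 (21 adjusted over the list alone, adjusted p = 3.31e-42, median log2 difference -5.61, -5.48 with genes at 0 in 1 gate held at their bound), with Tbx21, Eomes and Ifng. The macrophage list did not pass (adjusted p = 0.117), yet the complement genes C1qa, C1qb and C1qc and Csf1r rose, while Tyrobp, Fcer1g and Fcgr3 fell. Whether RNA from macrophages in the BCL11b+ID2+ gate adds to the higher genes was not tested for this comparison. Gamma-delta genes rose in 8 of 19 (8 adjusted over the list alone, adjusted p = 4.17e-09). Alpha-beta genes rose in 2 of 15 with 1 moving the other way (4 adjusted over the list alone, adjusted p = 0.00133), Themis among them. Genes of innate lymphoid precursors rose in 5 of 16 with 1 moving the other way (7 adjusted over the list alone, adjusted p = 0.00131). Cytokine receptors rose in 10 of 26 with 3 moving the other way (11 adjusted over the list alone, adjusted p = 0.00011). Cytokine and effector genes fell in 8 of 20 with 2 moving the other way (8 adjusted over the list alone, adjusted p = 0.000105). Type 3 ILC genes rose (adjusted p = 0.0131, adjusted p = 0.088 with an estimated correlation), and so did glycolysis genes (adjusted p = 0.000737, adjusted p = 0.255 with an estimated correlation). Mitochondrial genes rose (adjusted p = 0.00303, adjusted p = 0.29 with an estimated correlation). Dendritic cell genes fell (adjusted p = 0.00241, adjusted p = 0.0856 with an estimated correlation). Mast and erythroid genes fell (adjusted p = 0.00776, adjusted p = 0.0727 with an estimated correlation), with Cpa3, Ms4a2, Mcpt8 and Car2. Of all genes 835 changed, 437 higher and 398 lower. Here too lower genes led under TMM scaling, 418 higher to 425 lower, with only the groups compared, 491 to 529, and without libraries 1, 2 or 4 of BCL11b+ID2+, 292 to 323, 285 to 317 and 283 to 289. Without BCL11b-ID2+ library 2 or 4 the count was 510 or 522.

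**Figure D3:**
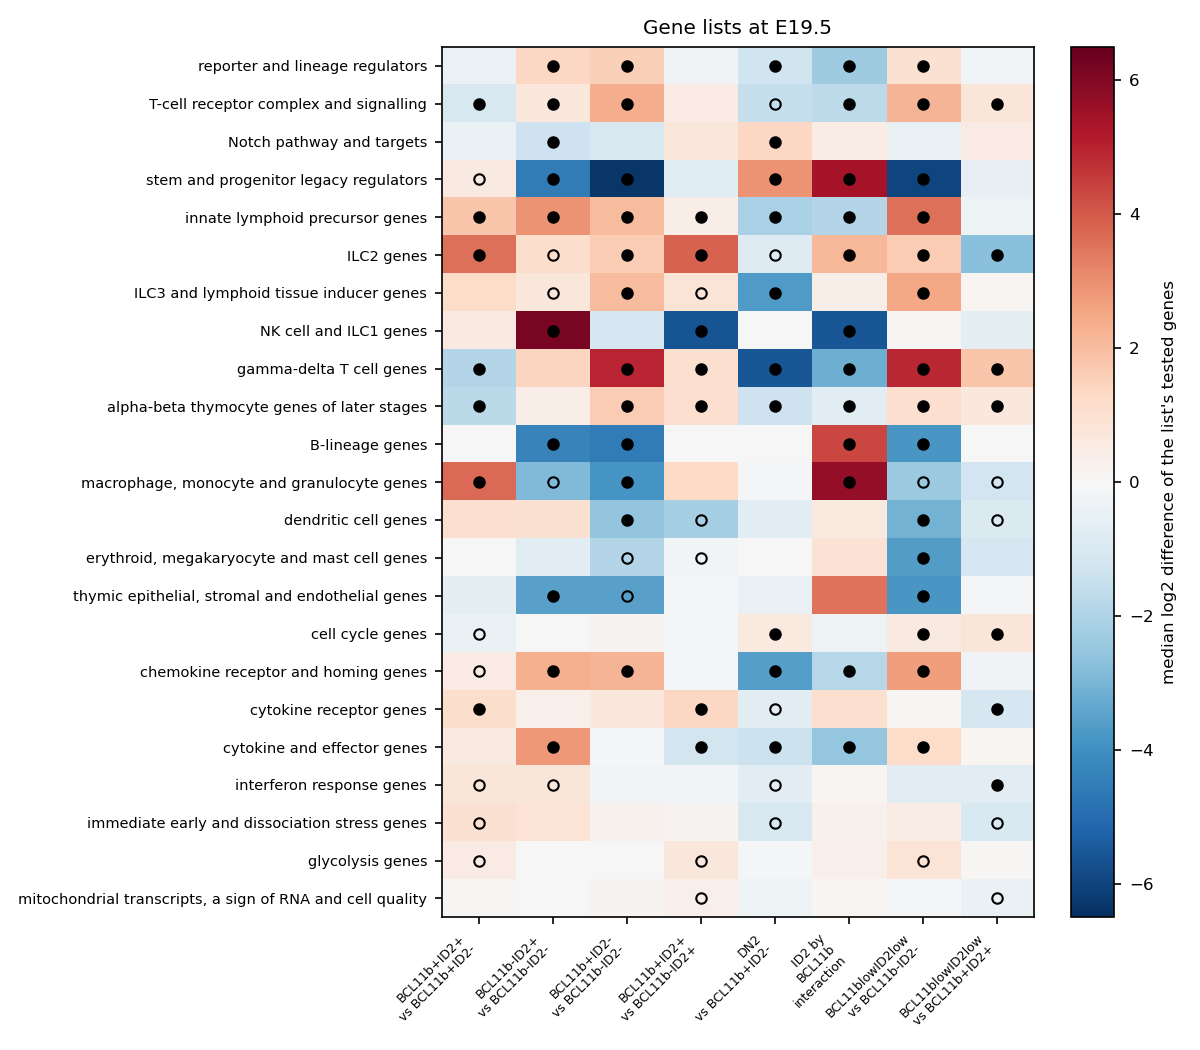
Median log2 difference of each of the 23 gene lists (colour) in the 8 comparisons of E19.5. Filled circles mark lists past the threshold with the preset and the estimated correlation, and open circles those past it with the preset one only. NK cell and ILC1 genes, for example, have medians of 6.15 in BCL11b-ID2+ against BCL11b-ID2- and -5.61 in BCL11b+ID2+ against BCL11b-ID2+.

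DN2 cells of E19.5, set against BCL11b+ID2- DN1 cells, had more progenitor and Notch transcripts and fewer gamma-delta and homing transcripts. With progenitor transcripts higher in DN2, the comparison cannot be read as a simple step from DN1 to DN2. Erg had 352 ± 128 in DN2 and no reads in the DN1 gate, at least 203-fold higher (adjusted p = 1.32e-05). The cell cycle inhibitor gene Cdkn1a rose by 7.86 on the log2 scale, and Bcl11a rose 818-fold (95% counting interval 147 to 32312). Ikzf3, a lymphoid zinc-finger factor, was 530.0-fold lower at 3.67 ± 2.04 against 1944 ± 985 (log2 difference -8.67 ± 0.34 SE, adjusted p = 4.51e-14), and Ccr9, a thymus homing receptor, 213-fold lower at 42 ± 10.2 against 8967 ± 1805. Emilin2 and Map3k20 also rose, and Ccr8 and Blk fell. Progenitor regulators rose in 10 of 19 (12 adjusted over the list alone, adjusted p = 2.71e-11). Notch genes rose in 5 of 9 (5 adjusted over the list alone, adjusted p = 8.76e-05), with Il2ra, Ptcra and Hes1. Cell cycle genes rose in 7 of 29 (7 adjusted over the list alone, adjusted p = 0.000142), with Mcm5, Pcna and Ccne2. Gamma-delta genes fell in 16 of 19 with 1 moving the other way (17 adjusted over the list alone, adjusted p = 5.73e-18). Homing genes fell in 18 of 24 with 2 moving the other way (18 adjusted over the list alone, adjusted p = 2.82e-14) and type 3 ILC genes in 12 of 18 with 2 moving the other way (12 adjusted over the list alone, adjusted p = 1.85e-05). Genes of innate lymphoid precursors fell in 9 of 16 with 1 moving the other way (10 adjusted over the list alone, adjusted p = 7.76e-07). Lineage regulators fell in 13 of 26 with 3 moving the other way (14 adjusted over the list alone, adjusted p = 5.03e-06). Cytokine and effector genes fell in 7 of 20 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 0.00444). Alpha-beta genes fell in 8 of 15 with 2 moving the other way (10 adjusted over the list alone, adjusted p = 0.00166), with Rag1 and Rag2 higher. T-cell receptor genes fell (adjusted p = 0.00211, adjusted p = 0.0737 with an estimated correlation), as did ILC2 genes (adjusted p = 0.0372, adjusted p = 0.0592 with an estimated correlation). Cytokine receptors fell (adjusted p = 0.00303, adjusted p = 0.0845 with an estimated correlation). Falls were also seen for interferon response genes (adjusted p = 0.0363, adjusted p = 0.217 with an estimated correlation) and immediate early genes (adjusted p = 0.0155, adjusted p = 0.431 with an estimated correlation). In this comparison 2240 genes changed, 937 higher and 1303 lower.

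The interaction at E19.5 asks for which genes the ID2 difference depended on BCL11b, and 1284 genes passed, 633 with a more positive and 651 with a more negative ID2 difference among BCL11b-positive cells. Gzma had a strongly negative value (-12.18 ± 0.44 SE on the log2 scale, adjusted p = 8.84e-15), falling with ID2 in BCL11b-positive cells (-6.06) and rising in BCL11b-negative cells (6.12). Ccl1, Ccr8 and Klrc1 were also more negative. Mrc1, Csf1r, Il1rl1 and Mpo were more positive, with Il1rl1 at 9.62 ± 0.99 SE and Mpo, which differed in the BCL11b-negative cells, at 9.93 ± 1.15 SE. NK cell genes were more negative in 17 of 22 with 1 moving the other way (18 adjusted over the list alone, adjusted p = 2.18e-17), and gamma-delta genes in 13 of 19 with 1 moving the other way (14 adjusted over the list alone, adjusted p = 7.97e-12). T-cell receptor genes were more negative in 11 of 22 with 2 moving the other way (13 adjusted over the list alone, adjusted p = 2.82e-12). Lineage regulators were so in 15 of 26 with 3 moving the other way (15 adjusted over the list alone, adjusted p = 2.39e-07). Progenitor regulators were more positive in 13 of 19 (16 adjusted over the list alone, adjusted p = 1.25e-16), and macrophage genes in 12 of 18 (13 adjusted over the list alone, adjusted p = 3.9e-11). ILC2 genes were more positive in 7 of 22 with 3 moving the other way (8 adjusted over the list alone, adjusted p = 0.000166) and B-lineage genes in 6 of 9 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 5.96e-05). Genes of innate lymphoid precursors were more negative in 8 of 16 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 2.83e-05). Homing genes were more negative in 10 of 24 with 3 moving the other way (11 adjusted over the list alone, adjusted p = 0.000303). Cytokine and effector genes were so in 10 of 20 with 2 moving the other way (10 adjusted over the list alone, adjusted p = 0.000176). Alpha-beta genes were so in 3 of 15 with 1 moving the other way (3 adjusted over the list alone, adjusted p = 0.00296). More called values were positive than negative without the filter, 584 positive to 573 negative, without libraries 1 or 2 of BCL11b+ID2-, 499 to 480 and 605 to 528, and without libraries 1, 2 or 4 of BCL11b-ID2+, 504 to 435, 464 to 447 and 479 to 469. Each interaction value is a difference of differences, so a gene can pass because it moves in only 1 of the BCL11b states.

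The BCL11blowID2low gate of E19.5 was compared first with the BCL11b-ID2- gate. Tcrg-V6 (chromosome 13, 19190356 to 19190929, GRCm38), another gamma-chain segment, had 388 ± 62.5 in the low gate and no reads in BCL11b-ID2-, at least 318-fold higher (adjusted p = 9.48e-08). Il23r, the IL-23 receptor gene, rose 387-fold to 744 ± 212, Cxcr6 424-fold and the scavenger receptor gene Cd163l1 of gamma-delta cells 145-fold. Mpo and Cd34, a surface marker of blood progenitors, were 1057-fold and 591-fold lower, with Cd34 at 1.82 ± 1.65 against 1077 ± 149 (log2 difference -8.81 ± 0.76 SE). Ccr4, Map1b and Mmp25 also rose, and Alox5ap, Car2 and Flt3 fell. Gamma-delta genes rose in 17 of 19 with 1 moving the other way (17 adjusted over the list alone, adjusted p = 6.39e-25, median log2 difference 4.92, unchanged with genes at 0 in 1 gate held at their bound). Precursor genes of innate lymphoid cells rose in 13 of 16 with 1 moving the other way (15 adjusted over the list alone, adjusted p = 1.28e-15). T-cell receptor genes rose in 13 of 22 with 2 moving the other way (14 adjusted over the list alone, adjusted p = 5.36e-13). Type 3 ILC genes rose in 10 of 18 with 1 moving the other way (11 adjusted over the list alone, adjusted p = 1.66e-08). Homing genes rose in 16 of 24 with 4 moving the other way (16 adjusted over the list alone, adjusted p = 8.94e-11). Lineage regulators rose in 12 of 26 with 2 moving the other way (15 adjusted over the list alone, adjusted p = 1.4e-08). ILC2 genes rose in 8 of 22 with 2 moving the other way (11 adjusted over the list alone, adjusted p = 0.000101). Alpha-beta genes rose in 5 of 15 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 0.00327). Cytokine and effector genes rose in 6 of 20 with 2 moving the other way (6 adjusted over the list alone, adjusted p = 0.0283). Cell cycle genes rose in 8 of 29 (9 adjusted over the list alone, adjusted p = 1.19e-05). Progenitor regulators fell in 18 of 19 (18 adjusted over the list alone, adjusted p = 1.24e-20). B-lineage genes fell in 5 of 9 (7 adjusted over the list alone, adjusted p = 0.000107). Dendritic cell genes fell in 7 of 12 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 0.000184). Stromal genes fell in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.000101). Mast and erythroid genes fell in 6 of 11 (6 adjusted over the list alone, adjusted p = 4.39e-06). Glycolysis genes, Eno1 and Ldha among them, rose (adjusted p = 2.02e-05, adjusted p = 0.151 with an estimated correlation). Macrophage genes fell (adjusted p = 0.000411, adjusted p = 0.0858 with an estimated correlation). The count was 1944 genes, 927 higher and 1017 lower, around a median log2 difference of all genes of -0.14. Higher genes were the more numerous with edgeR, 884 higher to 697 lower, with DESeq2, 1069 to 932, and without libraries 1, 2 or 4 of BCL11b-ID2-, 772 to 682, 691 to 649 and 722 to 653.

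Against the BCL11b+ID2+ gate, the BCL11blowID2low gate had fewer ILC2 transcripts. Il1rl1 was 2091-fold lower at 1.73 ± 0.655 against 3624 ± 389 (log2 difference -10.40 ± 0.70 SE, adjusted p = 1.72e-09), and Calca, Hlf and Tnfrsf19 were 489-fold (95% counting interval 167 to 2373), 85.1-fold and 960.1-fold (95% counting interval 172 to 37923) lower. Cxcr5, a follicle homing receptor, was 268-fold (95% counting interval 91.9 to 1302) higher. Ighm, the IgM heavy chain, stood at 1359.8 ± 249 against 34 ± 10.4 (adjusted p = 6.74e-10), and Tcrg-V6 at 388 ± 62.5 against 26.2 ± 16.8 (adjusted p = 0.0031). Pou2af1, Ccr7, Sox13, Il1r1 and Blk also rose, and Pde7b and Thsd4 fell. ILC2 genes fell in 11 of 22 (16 adjusted over the list alone, adjusted p = 5.73e-18). Cytokine receptors fell in 8 of 26 with 1 moving the other way (14 adjusted over the list alone, adjusted p = 1.43e-05). Interferon response genes fell in 2 of 20 (5 adjusted over the list alone, adjusted p = 0.000234). Gamma-delta genes rose in 8 of 19 (10 adjusted over the list alone, adjusted p = 2e-14). T-cell receptor genes rose in 5 of 22 with 1 moving the other way (8 adjusted over the list alone, adjusted p = 8.92e-07). Alpha-beta genes rose in 4 of 15 (4 adjusted over the list alone, adjusted p = 0.00216). Cell cycle genes rose in 8 of 29 (16 adjusted over the list alone, adjusted p = 3.3e-14), among them Aurka, Mki67 and Mcm2. Members of the B-lineage list other than Ighm were not called and the list did not pass (adjusted p = 0.0606). Macrophage genes fell (adjusted p = 0.00973, adjusted p = 0.207 with an estimated correlation), as did dendritic cell genes (adjusted p = 0.0178, adjusted p = 0.176 with an estimated correlation). Immediate early genes fell (adjusted p = 0.0131, adjusted p = 0.428 with an estimated correlation), as did mitochondrial genes (adjusted p = 0.00107, adjusted p = 0.243 with an estimated correlation). Here 613 genes changed, 202 higher and 411 lower. A fit of these 6 libraries alone called 341, and without BCL11b+ID2+ library 4 the count was 318. Of 245 named E19.5 calls, counted as for E15.5 and with those of the closing section, 25 were lost in at least 1 fit without a single library, 14 with DESeq2, 12 with edgeR, 10 with only the groups compared, 10 without the filter and 9 with library weights.

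**Figure D4:**
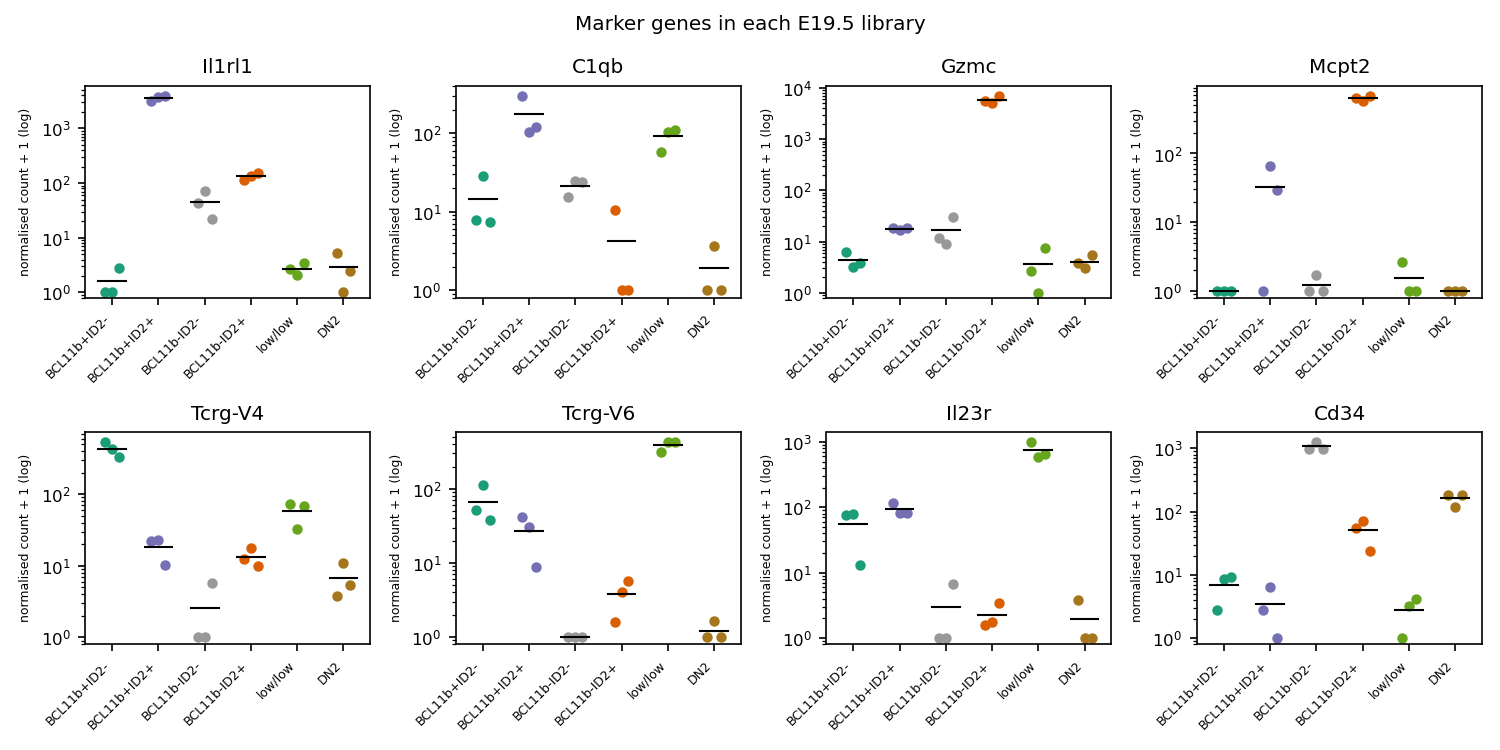
Normalised read counts plus 1 (log axes) of 8 marker genes in each E19.5 library, with a bar at each population's mean; the low/low gate is BCL11blowID2low. Il1rl1 and C1qb are highest in BCL11b+ID2+, Gzmc and Mcpt2 in BCL11b-ID2+, Tcrg-V4 in BCL11b+ID2-, Tcrg-V6 and Il23r in the low/low gate and Cd34 in BCL11b-ID2-.

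Levels at E15.5 and E19.5 were not tested against each other, because the deposited tables of the stages were normalised separately. The calls of the same gate comparison can be set side by side, since the stages share no library. Of the 48 genes called in BCL11b-ID2+ against BCL11b-ID2- at E15.5, all 48 had the same sign and were called at E19.5, 33 higher and 15 lower. Independent lists of these sizes would share 3.22 and 1.11 of 9935 genes tested at both stages. For BCL11b+ID2+ against BCL11b+ID2-, 60 of 74 had the same sign, and 17 higher and 16 lower genes were called at both, where 2.21 and 1.25 would be shared by independent lists. Of the genes named for it as higher, Adam12, Ankrd50, Myo6, Trio, Itgae, Rora and Maf were not called at E19.5. Nor were Erg, Akr1b3, Camk2a, Rag1 and Rag2 of the lower ones. Erg, Rag1 and Maf had the opposite sign there, with Erg at a log2 difference of 0.49 (adjusted p = 0.881). Ets1, the only gene called in BCL11b+ID2- against BCL11b-ID2- at E15.5, was called higher at both stages. Of the 8 genes of BCL11b+ID2+ against BCL11b-ID2+, 3 were called higher at both stages (Dpp4, Tcrg-C1 and Tcrg-C2) and 3 lower (Ncr1, Cpa3 and Cd200r4). The other 2, Cdk6 and Uprt, were not called at E19.5 (log2 differences 0.10 and -0.57, adjusted p = 0.912 and 0.738).

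**Figure D5:**
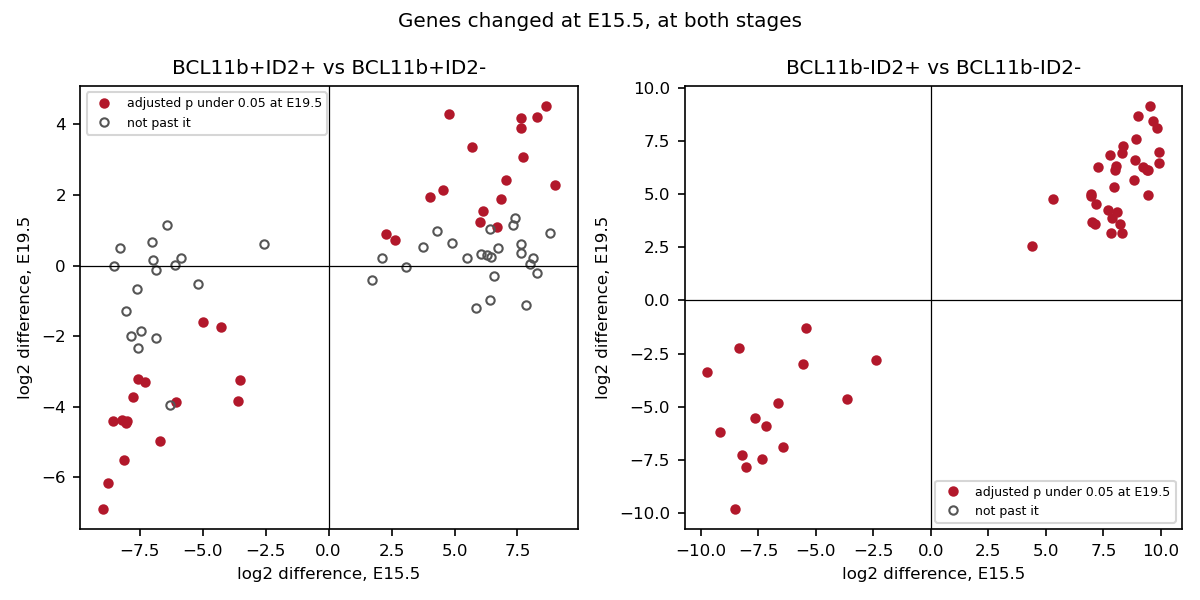
Log2 differences at E15.5 (x axis) and E19.5 (y axis) of genes called at E15.5 in the ID2 comparison among BCL11b-positive (left) and BCL11b-negative (right) DN1 cells; filled points were called at E19.5 too. All 48 genes of the right panel lie in the quadrants of equal sign, against 60 of 74 in the left.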

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

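Of the tests in this part, the tests of read numbers and of mitochondrial reads, the comparison of ILC2 with macrophage shares, the count of gamma-delta genes outside receptor segments and the splits of the libraries were chosen only after the results were seen.

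A difference between groups drew attention at E19.5, where the ID2 difference itself depended on BCL11b for 1284 genes by the interaction test. Of 100 random splits of the 12 libraries within their BCL11b states, the real one included, 2 gave as many genes. Mixed splits break up the ID2 differences as well as their dependence on BCL11b. The share of 2 in 100 therefore cannot exclude chance for the interaction. The highest other split gave 2203 genes, and that number equals the count for the sum of the ID2 differences over the BCL11b states, 2203. That split thus follows a structure of the samples, the ID2 gates themselves.

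Macrophage genes were higher in the BCL11b+ID2+ gate than in the BCL11b+ID2- gate of E19.5. RNA from macrophages, sorted with the gate in amounts that vary between libraries, is a possible account. The list's members moved together within gates over the 18 libraries of E19.5. Their mean correlation was 0.132, at percentile 99.9 of 1000 matched lists (95th percentile 0.059). This value is pooled over all gates and set against random genes, so it cannot decide the question for the BCL11b+ID2+ gate. If the macrophage-list transcripts of the BCL11blowID2low gate come from the same macrophage RNA, the tables argue against that RNA bringing the ILC2 genes. Where those transcripts come from was not tested. In the BCL11blowID2low libraries the 12 called ILC2 genes lay lower, relative to the BCL11b+ID2+ gate, than the 13 called macrophage genes, by a mean log2 difference of -2.93 (SD 0.845, 3 libraries). A biological difference between the gates, including ILC2-like cells that express some macrophage genes, stays open as untested.

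Gamma-delta T cell genes were higher in the BCL11b+ID2- gate than in the BCL11b-ID2- gate of E19.5. Reads shared between near-identical receptor segments cannot be the whole cause, because 10 of 11 members that are not receptor segments were called higher, with a median log2 difference of 5.46. RNA from a varying number of gamma-delta T cells in the gate may contribute and cannot be told apart from a programme of the gate's own cells: members correlated within gates at 0.0413, percentile 93.9 of matched lists, just under their 95th percentile of 0.0435. Whether the gate holds committed gamma-delta cells is a hypothesis that bulk libraries do not settle.

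Replicate libraries correlated less at E15.5 than at E19.5. Fewer reads are not the cause, because the shallowest E15.5 library held 1.27 times the reads of the deepest E19.5 library. The reads taken by mitochondrial RNA are not either. With them left out and the E19.5 libraries reduced to 1762514 reads, fewer than the 3393061 of the shallowest E15.5 library, the lowest correlation between E19.5 replicates was 0.821, against a highest of 0.658 at E15.5. Few starting molecules at E15.5 may be a cause, but the log-log slope of the squared coefficient of variation on the mean, -0.343 ± 0.0156 SE against -0.314 at E19.5, does not decide it, and a real difference between the embryos at E15.5 stays open as untested.

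The 3-against-3 comparisons have 10 splits of their libraries, so a share under 0.05 is impossible. In each of them only the real split, 1 of 10, reached its count. Every other split mixes libraries of both populations within each group. Where the populations differ, mixing widens the spread and shrinks the difference, so low counts in those splits cannot exclude chance. At E15.5 the real counts and highest other splits were 74 and 5 for BCL11b+ID2+ against BCL11b+ID2-, 48 and 0 for BCL11b-ID2+ against BCL11b-ID2-, 1 and 0 for BCL11b+ID2- against BCL11b-ID2-, and 8 and 0 for BCL11b+ID2+ against BCL11b-ID2+. At E19.5 the same comparisons gave 1208, 2194, 2067 and 835 against 0 in every other split, and DN2 against BCL11b+ID2- gave 2240 against 0. The BCL11blowID2low gate gave 1944 against BCL11b-ID2- and 613 against BCL11b+ID2+, each with a highest other of 1. At E15.5 the interaction called 0 genes with limma (662 at an unadjusted p under 0.05, 0 with edgeR and 392 with DESeq2). Since the real count was 0, all 100 splits had to give as many, so they say nothing about chance. The highest gave 212, again the count for the sum of the ID2 differences.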

How the results depend on the processing

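The comparison of the BCL11blowID2low gate with the BCL11b+ID2- gate was added after the data were seen, as were its alternatives; the other alternatives were chosen before the data were examined. The planned difference between E19.5 and E15.5 over the shared gates and the stage difference of the gate effects were not run. Depth limits genes near the floor of 3 reads at both stages, and at E15.5 the spread between libraries left most simulated changes uncalled, with 7 of 48 genes changed 32-fold recovered by limma for BCL11b+ID2+ against BCL11b+ID2-.

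Counts of changed genes at E15.5 depended on the processing, and the cause was not tested. For BCL11b+ID2+ against BCL11b+ID2- (74 genes) the count was 21 without the filter, 1089 with DESeq2 (72 shared), 2 with only the groups compared and 25 with library weights. For BCL11b-ID2+ against BCL11b-ID2- (48) these were 28 without the filter, 414 with DESeq2 and 146 with weights. The count of 1 for BCL11b+ID2- against BCL11b-ID2- became 0 with pseudocount 8, no filter, TMM scaling, edgeR, only the groups compared and the replicate block, 335 with DESeq2 and 6 with weights. The 8 for BCL11b+ID2+ against BCL11b-ID2+ became 19 with pseudocount 8, 5 without the filter, 634 with DESeq2, 0 with only the groups compared and 5 with weights. DESeq2 called 532 for DN2 and 392 for the interaction, where limma called 0 and edgeR 0, with 663 and 662 genes at an unadjusted p under 0.05.

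At E19.5 the counts of the planned comparisons stayed within 1.5 times under every alternative except BCL11blowID2low against BCL11b+ID2+ with only the groups compared (341, 292 shared) and the left-out libraries below. The added comparison moved from 957 to 298 with only the groups compared and 546 with weights.

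Leaving out 1 library at a time gave, at E15.5, 15 to 82 genes for BCL11b+ID2+ against BCL11b+ID2-. Libraries 1, 2 and 3 of BCL11b+ID2- gave 23, 21 and 26, and 1 and 3 of BCL11b+ID2+ 22 and 15. BCL11b-ID2+ against BCL11b-ID2- gave 4 to 15, with 15, 11 and 4 without BCL11b-ID2- 1, 2 and 3, and 9, 10 and 8 without BCL11b-ID2+ 1, 2 and 3. BCL11b+ID2- against BCL11b-ID2- gave 0 to 6, with 6 without BCL11b+ID2- 1 and 0 without each of the other 5. BCL11b+ID2+ against BCL11b-ID2+ gave 3 to 8, with 4 without BCL11b+ID2+ 3 and 3, 4 and 4 without BCL11b-ID2+ 1, 2 and 3. DN2 gave 0 to 3, with 3 without BCL11b+ID2- 1 and 1 without DN2 1, where the lone DN2 library is assumed to vary like the other groups. The interaction gave 0 to 1, with 1 without BCL11b+ID2+ 1. At E19.5 the ranges were 795 to 1050 for BCL11b+ID2+ against BCL11b+ID2- (795 without BCL11b+ID2- 1 and 801 without BCL11b+ID2+ 4) and 1556 to 1696 for BCL11b-ID2+ against BCL11b-ID2-. They were 1417 to 1961 for BCL11b+ID2- against BCL11b-ID2-, and 510 to 615 for BCL11b+ID2+ against BCL11b-ID2+ (510 and 522 without BCL11b-ID2+ 2 and 4). DN2 gave 1544 to 2059, the interaction 899 to 1203 and BCL11blowID2low against BCL11b-ID2- 1340 to 1993. BCL11blowID2low against BCL11b+ID2+ gave 318 to 631, with 355, 405 and 318 without BCL11b+ID2+ 1, 2 and 4 and 374 without BCL11blowID2low 2. The added comparison gave 481 to 889, with 481 without BCL11b+ID2- 1. In it the uncalled Il17a, at 0.12 on the log2 scale, became -0.12, -0.13 and 0.62 without BCL11b+ID2- 1, 2 and 4 and -0.20 without BCL11blowID2low 4. The uncalled Tcrg-V1, at 0.43, became -0.0492 and 0.689 without BCL11blowID2low 1 and 4, and Tcrg-V5, at -0.04, 0.0168 without BCL11b+ID2- 2 and 0.0025 without BCL11blowID2low 4. Tcrg-C4, at -0.04, became 0.0035 with edgeR and -0.11 and 0.0902 without BCL11blowID2low 2 and 4.

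With an estimated correlation, the number of lists past the threshold fell at E15.5 from 10 to 5 for BCL11b+ID2+ against BCL11b+ID2-, 11 to 7 for BCL11b-ID2+ against BCL11b-ID2-, 10 to 4 for BCL11b+ID2- against BCL11b-ID2-, 8 to 5 for BCL11b+ID2+ against BCL11b-ID2+, 2 to 0 for DN2 (1 with the block) and 4 to 2 for the interaction. At E19.5 it fell from 13 to 7 for BCL11b+ID2+ against BCL11b+ID2-, 12 to 7 for BCL11b+ID2+ against BCL11b-ID2+ and 11 to 7 for BCL11blowID2low against BCL11b+ID2+. Of 45 list calls at E15.5, 23 held with an estimated correlation and 42 with a block for the library number. Of 108 at E19.5, 80 and 107 held, and 1 was gained with the block.

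No label says what libraries with the same number share. Correlations of residuals of same-number pairs ran from -0.0458 to 0.0388 at E15.5 (0 of 26 over 0.1) and from 0.00202 to 0.129 at E19.5 (1 of 45). As a hint from the data only, 10 of 14 and 17 of 18 libraries correlated best with their own number. Sex-linked transcripts, looked at after the other results, followed the number in part. At E19.5 the same number had the highest Xist in 6 and the lowest sum of 4 Y-linked genes in 6 of 6 populations, and at E15.5 the same number had the highest Y-linked sum in 5 of 5 but the highest Xist in no more than 2. The highest Y-linked sum fell on the same number in no more than 4 of 6 populations at E19.5, and the lowest in no more than 3 of 5 at E15.5. Libraries of a number may thus share embryos, which the labels do not state. The block gave 59, 36, 0, 7, 0 and 0 genes at E15.5, with the comparisons in the order just used for the lists, and 770 to 2577 over the planned comparisons of E19.5, counts within 1.5 times of those without it apart from 1 that became 0. Of 71 named E15.5 calls, 14 were lost with the block. For BCL11b+ID2+ against BCL11b+ID2- these were Akr1b3, Clnk, Cxcr6, Itgae, Ptprf and Trio, for BCL11b-ID2+ against BCL11b-ID2- Arg1, Bpifc, Cxcr6, Itga1, Itih5 and Spns2, and for the BCL11b comparisons Ets1 and Ncr1.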

Other observations

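The comparison of the BCL11blowID2low gate with the BCL11b+ID2- gate of E19.5 was chosen only after the receptor segment levels of these gates had been seen, as were the genes named for it. The test by splits was chosen before the count was known.

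The BCL11blowID2low and BCL11b+ID2- gates of E19.5 differed in some gamma-delta receptor segments (n = 3 each). The gamma segment Tcrg-V6 stood at 388 ± 62.5 against 66.2 ± 39.7 normalised counts (log2 difference 2.68 ± 0.80 SE, adjusted p = 0.0458). The delta segment Trdv4 (chromosome 14, 54074905 to 54075515, GRCm38) stood at 578 ± 124 against 97.3 ± 69.8 (adjusted p = 0.00783). In the other direction, Tcrg-V4 stood at 56.8 ± 22.2 against 431 ± 98.1 (log2 difference -2.97 ± 0.76 SE, adjusted p = 0.019) and Trdv5 at 3.92 ± 2.45 against 133 ± 28.9 (adjusted p = 0.00168). The delta constant gene Trdc, at 2509.8 ± 512 against 2971 ± 339, was not called (adjusted p = 0.633). The variable segments Tcrg-V1, Tcrg-V5 and Trgv2 were not called either (adjusted p = 0.796, 0.991 and 0.74), nor were the constant genes Tcrg-C1, Tcrg-C2 and Tcrg-C4 (0.721, 0.269 and 0.985). Segments of this family are similar, and reads may be divided among them. That uncertainty was tested for the gamma-delta list only, where 10 members outside the receptor segments were called higher in BCL11b+ID2- against BCL11b-ID2-.

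Regulators and surface receptors differed with the segments. Il23r, a receptor gene of IL-17-producing cells, stood at 744 ± 212 against 54.9 ± 37.2 (4.09 on the log2 scale, adjusted p = 0.00553). Zbtb16, which encodes the innate-like T cell factor PLZF, stood at 673 ± 261 against 157 ± 49 (adjusted p = 0.0222), and Ccr6, Cxcr6, Cd163l1 and Id2 were also higher, by 3.05, 2.75, 1.64 and 3.67 on the log2 scale. Etv5, Gzma, Cpa3, Cd27, Gata3, Tcf7, Notch3, Ccr9 and Bcl11b were lower, with Gzma at 207 ± 32.4 against 4968 ± 557 (adjusted p = 6.64e-09), Cd27 at 283 ± 110.0 against 1442 ± 219.9 (adjusted p = 9.18e-05) and Bcl11b at 448 ± 62.5 against 1674 ± 348 (adjusted p = 0.0232). Il17a, at 55 ± 25.9 against 52.8 ± 35, was not called. In all 957 genes changed in limma, 424 higher and 533 lower in the BCL11blowID2low gate. The excess of lower genes turned with edgeR, 385 higher to 351 lower, and without library 2 of BCL11b+ID2-, 427 to 380.

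As a hypothesis that was not tested, these gates may hold gamma-delta cells that use different segments, with the low gate holding more Tcrg-V6 and Trdv4 cells and the BCL11b+ID2- gate more Tcrg-V4 and Trdv5 cells. Bulk libraries cannot show which segments a cell uses, and receptor sequences of single cells from each gate would decide it. The values that follow concern only the number of changed genes. Only the real split of the 6 libraries, 1 of 10, gave 957 genes, the highest other gave 3, and a share under 0.05 is impossible with 10 splits. The other splits mix both gates within each group, so their low counts cannot exclude chance. With only the 6 libraries in the fit the count was 298, and without BCL11b+ID2- library 1 it was 481. A mixture of cell types within either gate was not tested for this comparison.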
